A study of Homo sapiens with 4 samples.

How the data were processed

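The labels describe 4 libraries from unmodified HCCLM3 cells, 2 of YTHDF2 RIP and 2 of input, made with a magnetic-bead RIP kit and a stranded total RNA library kit for low input, per the labels' protocols. Groups and replicate numbers came from the labels. Nothing says whether the replicates came from separate cultures, and how the authors combined the libraries into 1 peak list is not given in the sources used here. HISAT2, MACS2 and the hg38 build are named in the submitters' processing notes, and their versions, options and thresholds are not given in the sources used here.

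The deposited list gives, per the file headers, each peak's position, width, summit offset, score, fold enrichment, −log10 p and −log10 q, a transcript feature, and the gene of the nearest transcription start site. The fold enrichment is the authors' ratio of RIP to background at the summit. The −log10 p and −log10 q are the authors' values and were used only to describe, rank and filter peaks within the list. The authors' score equalled 10 times the −log10 p, rounded down, and was not used further. The width of each peak in bp is as deposited and had a median of 349 and a minimum of 315, shared by 4402 peaks. The lowest −log10 p in the list was 1.30. Peaks on all contigs were kept.

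In the caller's arithmetic the fold is (k + 1) / (background + 1), and the p is the Poisson probability of more than k fragments at that background. Solving both for a whole number k gave the RIP fragments and the background at each summit. The recovered values met every peak's −log10 p within 0.000189. The next best whole number was always much farther off, with the best residual at most 2.69% of it. On 2000 simulated peaks the simulated number was recovered in 100% of cases. The commonest backgrounds were 0.533 (2573 peaks), taken as the genome-wide level, and 0.68 (1715 peaks), taken as 1 scaled input fragment. These recovered numbers are values of the combined libraries at summits and not library depths, which are unknown here.

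Gene names came from the deposited gene numbers through a RefSeq gene table of the GRCh38.p14 assembly, which matched 99.9% of peaks and named 1730 of the 1737 peaks without a deposited symbol. Gene spans of the list and the table overlapped for 99.3% of 8686 genes. The deposited gene often differed from the gene holding the peak. It was the gene in the exon annotation for 57.2% of exon peaks, and the summit lay inside it for 46.8% of 3' UTR peaks. For gene lists and named genes each peak was therefore given to the gene named in the exon or intron annotation. Other peaks were given to the gene whose span contained the summit, protein-coding genes first, then the deposited gene, then the shortest gene. Of 3' UTR peaks, 7.07% had several candidate genes, since the table gives no strand and overlapping genes cannot be told apart. This assignment was chosen after seeing the list and before any gene list result was computed, and the deposited assignment was run as an alternative. Peaks per gene used the deposited assignment, as planned.

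Feature shares have exact Clopper-Pearson 95% intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The 3' UTR share in the top and bottom 25% of peaks by fold, and the share of genes with 2 or more peaks, were compared with Fisher's exact test, two-sided. Median log2 folds of feature classes and of gene lists were compared with two-sided permutation tests of 100000 resamples, adjusted by Benjamini-Hochberg over 2 feature comparisons and over the 19 lists with at least 5 members with a peak. The background for lists was all genes with a peak. How many members had a peak carries no enrichment test, because which genes were expressed is not known from a peak list. Peaks and genes are not replicates of the experiment. On simulated data, 5.67% of 300 unchanged lists of 20 genes and 97.7% of lists shifted by 0.5 on the log2 scale had a permutation p under 0.05. For the feature test these shares were 5.5% of unchanged sets and 100% of sets shifted by 0.1.

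The rule for named genes, fixed before the data were examined, was YTHDF2 and CRTC2, the 10 genes with the highest fold of an exon or UTR peak (protein-coding where the type is known), the 10 genes with the most peaks, and in each list up to 4 members with the highest best-peak fold. Some items that this rule takes are not reported here. ND4, UQCRFS1, WTAP, FTO, METTL3, MYC, MET, SLC39A1 and PPP1R18, the genes leading by −log10 q and those with the most peaks at a q of 0.01 or less were added after their values were seen. A peak passed with a q of 0.01 or less, a gene with such a peak, and a list or comparison with an adjusted permutation p, or a Fisher p, under 0.05. Alternatives covered stricter q and fold thresholds, main chromosomes, other summaries, matched random lists and the other gene assignment. Random lists matched on background were drawn within 10 groups of background level, so some difference in background can remain. The planned comparisons of peak position around the stop codon and of the DRACH motif, and a strand-aware annotation, need a genome and transcript models, which were not used here. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.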

Results

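The series compared RNA immunoprecipitated with YTHDF2 against input RNA in HCCLM3 cells, a metastatic human hepatocellular carcinoma line. YTHDF2 is a cytosolic reader protein that binds N6-methyladenosine (m6A) and recruits the CCR4-NOT deadenylase to the RNA. In RNA immunoprecipitation sequencing (RIP-seq), an antibody pulls down the protein with its bound RNA, and the RNA is sequenced beside the input it was taken from. The labels gave 4 libraries of unmodified cells, 2 of YTHDF2 RIP and 2 of input. None was a control pulldown, so a peak shows enrichment over input and not binding by itself. The processed data were 1 list of 14858 peaks in which RIP fragments exceeded the caller's background, which is the input after scaling to the RIP or the genome-wide level. The list held no value per library, so no replicate spread or sequencing depth could be given. Every permutation or Fisher p-value below measures the spread between peaks or genes within this list, the p and q of a single peak are the caller's, and every fold enrichment is the authors' value for that peak.

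The first comparison asked which RNAs were enriched in the YTHDF2 RIP over the input. The leading genes by −log10 q, taken on main chromosomes only, were chosen after their values were seen. RPL41, a protein of the large ribosomal subunit, led the protein-coding genes there with a fold of 7.95 and a −log10 q of 91.4 over a promoter-class peak on chromosome 12 (56117594 to 56118028, hg38). BOLA2B, an iron-sulfur chaperone with near-identical copies on chromosome 16, had a fold of 9.41. SNRPB, a core protein of spliceosomal snRNPs, had a fold of 8.34. The proline isomerase PPIA (fold 3.72), HINT1 (5.34), the membrane-binding annexin ANXA2 (3.83), the actin-nucleating subunit ARPC3 (4.86) and the lactate dehydrogenase subunit LDHB (5.04) had 3' UTR peaks. The growth factor MDK (fold 3.75) and the ribosomal stalk protein RPLP1 (5.93) had promoter-class peaks. YTHDF2 itself (chromosome 1, 28736624 to 28769775) and CRTC2 (chromosome 1, 153947675 to 153958612), a coactivator of CREB, had no peak overlapping the gene. The list named CRTC2 for 1 peak at 153959606 to 153959957, which lay upstream of CRTC2 and inside SLC39A1, a zinc transporter, with a fold of 1.48. A list of peaks holds no value for a gene without one, so this gives no level for YTHDF2 or CRTC2.

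By fold enrichment among exon and UTR peaks of protein-coding genes, RPS9, a protein of the small ribosomal subunit, ranked highest at 27.4-fold. Its peak lay in the 3' UTR on an alternative contig of chromosome 19 (182248 to 182681 of that contig). It was followed by exon peaks of NBPF19 (20.5-fold; chromosome 1, 149535614 to 149536033), IFNGR2, a chain of the interferon-gamma receptor (19.6-fold), PARN, a poly(A)-specific ribonuclease (17.0-fold), and DDX52, an RNA helicase (17.0-fold; chromosome 17, 37620627 to 37621477). Next were SINHCAF, a subunit of the SIN3-HDAC complex (16.7-fold; chromosome 12, 31297772 to 31298174), LOC102724594 (14.4-fold), DLG5 (13.0-fold), ABR, a GTPase-activating protein for RAC (12.5-fold; chromosome 17, 1091361 to 1091822), and BDP1, a subunit of TFIIIB (12.4-fold). The peaks of RPS9, IFNGR2, PARN, DLG5 and BDP1 lay on alternative contigs. The highest fold of the whole list, 35.2, was that of a promoter-class peak in PPP1R18, also on an alternative contig. Of all peaks, 323 lay on alternative, unplaced or random contigs.

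Most peaks were weak. The list ended at a p of about 0.05 per peak before adjustment, and 6635 peaks (44.7%) had a q of 0.05 or less, 5541 had a q of 0.01 or less, and 3454 had a −log10 q of 0. The median fold was 2.41, with a range of 1.15 to 35.2. The number of RIP fragments at each summit could be recovered from the fold and the p-value. Its median was 12 and its quartiles were 4 and 60, and 5086 peaks (34.2%) rested on 4 or fewer fragments. A single fold of 2.61, reached by 3 fragments over the genome-wide background, was shared by 1576 peaks.

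The next comparison asked where in the transcripts the peaks lay. The 3' UTR was the largest class with 4099 of 14858 peaks, or 27.6% (95% Clopper-Pearson interval 26.9 to 28.3). Introns held 3180 peaks (21.4%, 20.7 to 22.1), exons 3086 (20.8%, 20.1 to 21.4), promoters 2548 (17.1%, 16.5 to 17.8), distal intergenic sequence 1762 (11.9%, 11.3 to 12.4), the 5' UTR 173 (1.16%, 0.998 to 1.35) and downstream sequence 10. The intervals cover counting error only. In this annotation the promoter class holds peaks near a transcription start site, and 95.6% of promoter peaks had their summit inside a gene, so short mRNAs such as those of histones and ribosomal proteins fell largely into it. Among the 5541 peaks with a q of 0.01 or less, the 3' UTR share was 37.6% (36.4 to 38.9), the exon share 25.3%, and the intron share 4.17%. Median RIP fragments at the summit were 43 for 3' UTR, 47 for promoter, 18 for exon, 7 for 5' UTR, 4 for intergenic and 3 for intron peaks.

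**Figure D1:**
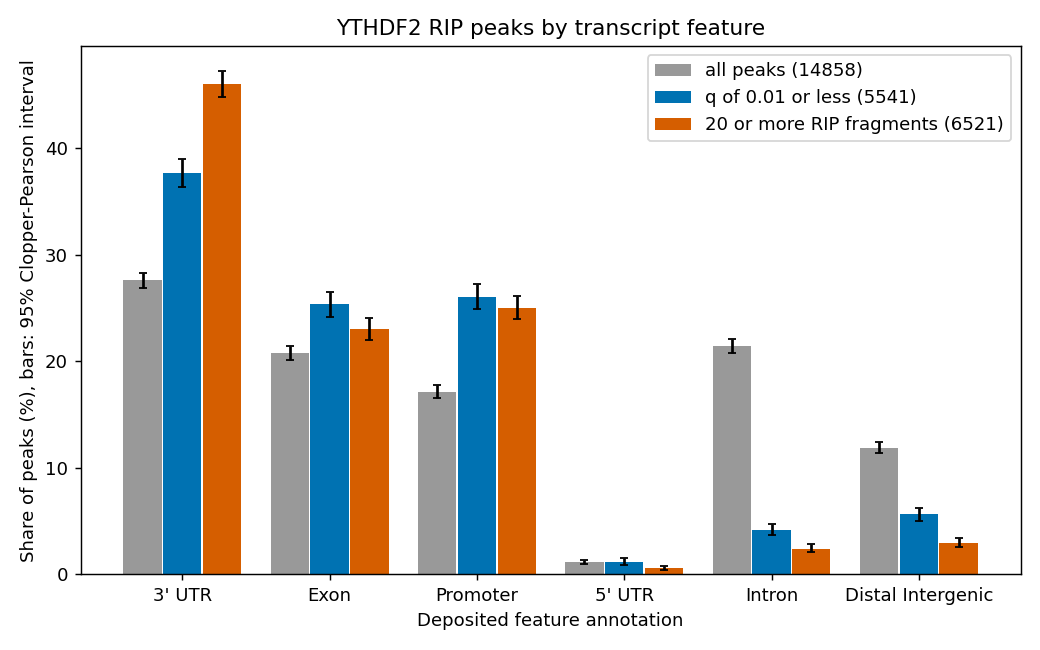
Bars give the share of peaks in percent (y axis) in each deposited feature class (x axis), for all 14858 peaks, the 5541 with a q of 0.01 or less, and the 6521 with 20 or more RIP fragments at the summit. Error bars are 95% Clopper-Pearson intervals. The 3' UTR share rises from 27.6% to 37.6% and 46.0%, while the intron share falls from 21.4% to 4.17% and 2.41%.

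Fold enrichment went the other way. Of the top 25% of peaks by fold, 741 of 3760 (19.7%) were 3' UTR peaks, against 1610 of 3728 (43.2%) in the bottom 25% (Fisher's exact test, two-sided, p = 7.23e-108, odds ratio 0.323). The difference in share of -23.5 percentage points was -8.67 at a −log10 q of at least 5, -7.66 among peaks with 20 or more fragments and 3.02 at a fold of at least 4 (Fisher's exact p = 0.396). Median folds were 2.13 for 3' UTR, 2.51 for exon and 2.61 for intron peaks. The median log2 fold of 3' UTR peaks was lower by a difference of -0.23 from exon peaks and of -0.29 from intron peaks. Both had an adjusted p of 1e-05 in two-sided permutation tests, the smallest the 100000 resamples can give. The list's p limit asks a higher fold of peaks with few fragments. The lowest fold among peaks of 3 fragments was 1.70, against 1.15 among peaks of 60 or more. Since fragment numbers differed by class, the tests over all peaks cannot tell a feature difference from the effect of this limit. Among peaks with 20 or more fragments the difference from exon peaks was 0.02 (adjusted permutation p = 0.292) and that from intron peaks was -0.48. Within groups of background level the difference from exon peaks was -0.053 and that from intron peaks was -0.016. This setting, like the one before, was chosen after seeing the data. No p-value is given for it, because labels shuffled within groups need not give equal medians, which the test assumed. At a fold of at least 4 the difference was -0.025 from exon and -0.031 from intron peaks, and neither passed (both adjusted permutation p = 0.487). That threshold filters on the compared value itself and left 192 3' UTR, 364 exon and 103 intron peaks, so it cannot decide. At a −log10 q of at least 5 the difference from exon peaks was -0.012 (adjusted permutation p = 0.633) and that from intron peaks was -0.55 (2e-05). With −log10 q as the measure 3' UTR peaks ranked above both classes.

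Gene lists fixed before the data were examined were compared by the best peak of each member, with each peak given to the gene that contains its summit. The best peak was that of highest fold, whatever its q. The median log2 fold of random lists was about 1.38, as is that of the 2.61-fold which 3 fragments reach over the genome-wide background. Summits lay in 7908 genes, 6959 of them protein-coding, and 3702 protein-coding genes had a peak with a q of 0.01 or less. Nuclear-encoded subunits of oxidative phosphorylation had higher folds than random genes with a peak. Of 36 listed genes, 24 had a peak and 20 had one with a q of 0.01 or less. Their median best-peak log2 fold was 1.77 against 1.38 for random lists (two-sided permutation test over 19 lists, adjusted p = 0.0159). The highest folds, all in 3' UTR peaks, were those of SDHB of complex II (6.68-fold; chromosome 1, 17018524 to 17018892), NDUFB3 of complex I (6.40-fold; chromosome 2, 201085565 to 201085908), COX6C of complex IV (5.66-fold; chromosome 8, 99887205 to 99887533) and NDUFA6 of complex I (5.25-fold; chromosome 22, 42085925 to 42086239). The lowest best peak in the list was the 3' UTR peak of UQCRFS1 (1.26-fold), which did not pass. At a q of 0.01 or less and on main chromosomes only, a setting chosen after seeing the data, the list's median log2 fold was 1.87 and it no longer passed, although the difference from random lists was 0.46 against 0.39 before (adjusted permutation p = 0.135). It also did not pass at a −log10 q of at least 5 (difference 0.43, adjusted permutation p = 0.0632) or with the mean over each gene's peaks (0.19, 0.18). At a fold of at least 4, which filters on the compared value itself, it did not pass either (0.25, 0.283). It passed with exon and UTR peaks only (0.51, 0.0123), against lists matched on peaks per gene (0.42, 0.00646) or on background level (0.54, 9.5e-05) and with the deposited gene (0.41, 0.0218), the last pair chosen after seeing the data.

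Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, had lower folds. Of 24, 13 had a peak and 12 had one with a q of 0.01 or less, and their median best-peak log2 fold was 0.85 (adjusted permutation p = 0.0159). H2AC20 had 2.69-fold over 324 fragments, the highest number of any peak, H4C3 2.56-fold, H2AC11 2.52-fold and H2AC8 2.33-fold. The members' best peaks had a median of 210 fragments over a background of 111. Whether the possible cap on pileup described in the closing section held these folds down was not tested. Against random genes matched on background level, a setting chosen after seeing the data, the histone list no longer passed. Its log2 difference there was -0.05 (adjusted permutation p = 0.878). This matching used 10 groups of background level, within which backgrounds can still differ, so it need not remove the whole effect of background. The difference from all random genes was -0.53. The list also did not pass when matched on peaks per gene (-0.42, adjusted permutation p = 0.0761), at a −log10 q of at least 5 (-0.29, 0.283) or at a q of 0.01 or less on main chromosomes (-0.44, 0.249). It passed with the mean over peaks (-0.41, adjusted permutation p = 0.0322) and with the deposited gene (-0.53, 0.0218). Each of the 13 genes had 1 peak, and the list's median fold was 1.81 in both settings, as in the main comparison. These passes are therefore no separate support.

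Most cytosolic ribosomal protein mRNAs had a peak. Of 79, 60 had 1 or more and 59 had one with a q of 0.01 or less, with a median best-peak fold of 2.66 over a median of 130 fragments. After RPS9, the highest were RPL41 (7.95-fold), RPLP1 (5.93-fold) and RPL27 (5.27-fold). The list did not differ from random genes (log2 difference 0.03, adjusted permutation p = 0.521). It was higher by 0.36 against genes matched on background level, a setting chosen after seeing the data, with an adjusted permutation p of 9.5e-05. With exon and UTR peaks only it was higher by 0.48 (adjusted permutation p = 0.0316). That setting drops promoter-class peaks, the class of most of the list's best peaks. It thus rests on fewer of the genes, and RPS9 with its peak on an alternative contig is among them. Translation initiation and elongation factors had a peak in 33 of 39 genes and one with a q of 0.01 or less in 32, with a median fold of 2.32, a log2 difference of -0.17 and an adjusted permutation p of 0.315. The list was lower with the mean over peaks (-0.29, adjusted permutation p = 0.0322) and against lists matched on peaks per gene (-0.25, 0.0481), and it was 0.16 higher, without passing, against lists matched on background level (0.358). EIF3C (5.92-fold), the cap-binding protein EIF4E (5.21-fold), EIF3H (4.76-fold) and EIF4G3 (4.24-fold) ranked highest among them. EIF3C has a near-identical copy, EIF3CL, so its reads are uncertain.

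Among m6A writers, erasers and readers, 18 of 24 genes had a peak and 13 had one with a q of 0.01 or less. YTHDC1, the nuclear m6A reader, had an exon peak of 5.87-fold over 8 fragments. VIRMA, a scaffold of the methyltransferase complex, had 4.32-fold, and YTHDF1, a paralog of YTHDF2, had 3.35-fold in its 3' UTR (chromosome 20, 63195276 to 63195656). The best peak of IGF2BP3 rested on 5 fragments. WTAP (2.95-fold), FTO (2.90-fold) and METTL3 (2.51-fold) had 3' UTR peaks with a q of 0.01 or less. Of 41 genes of deadenylation, decapping and decay, 30 had a peak and 21 passed that q. They were led by PARN (17.0-fold), PAN3 (5.95-fold over 9 fragments), the exonuclease XRN1 (5.09-fold over 11) and CNOT3 (4.17-fold over 6, on an alternative contig). Transcripts described earlier as regulated by m6A or YTHDF2 had a peak in 14 of 23 genes, 11 at that q. EGFR had 3.85-fold over 12 fragments, LATS1 2.60-fold and YAP1 2.47-fold, while the best peak of TNFRSF1B (2.63-fold) did not pass. MYC had 3 peaks that passed, the highest 2.27-fold over 197 fragments. The adjusted permutation p-values of these 3 lists were 0.704, 0.521 and 0.369.

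Of 30 genes recurrently altered in hepatocellular carcinoma, 24 had a peak and 17 passed a q of 0.01. Among the highest folds were those on APC (5.81), CDKN2A (4.98) and ACVR2A (4.15, over 6 fragments). In the CREB, CRTC and SIK axis, 15 of 24 genes had a peak and 8 passed. PPP3CB, a catalytic subunit of calcineurin, had 4.31-fold, SIK3 3.45-fold, CRTC3 3.30-fold, and SIK1 a peak of 4 fragments that did not pass. Of 36 genes of receptor tyrosine kinase, RAS-MAPK and PI3K signalling, 25 had a peak and 16 passed. PDPK1 had 3.95-fold, RICTOR 3.86-fold, EGFR 3.85-fold, and RPTOR a peak of 5 fragments that did not pass. MET, the hepatocyte growth factor receptor, had 6 peaks that passed. Of 15 lenvatinib target kinases and adaptors only GRB2, FRS2 and SOS1 had a peak, and only SOS1 passed (2.64-fold). Of 29 hepatocyte secreted proteins, FN1 (2.46-fold) and APOB (1.92-fold, not passing) had a peak. Of 20 markers of non-parenchymal and blood cells, HBB (5.87-fold over 8 fragments) passed, while PECAM1, LUM and CD68 had peaks that did not.

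Of 39 genes of Wnt and Hippo signalling, 25 had a peak and 15 passed a q of 0.01. They were led by APC, FZD6 (4.76-fold over 7 fragments), MOB1A (3.46-fold) and STK3 (3.29-fold in an intron peak that did not pass, beside a 3' UTR peak that did). Of 38 cell cycle genes, 28 had a peak and 19 passed, led by CCND3 (6.08-fold, intron), MCM5 (4.38-fold), CCNB2 (4.32-fold) and CDK4 (3.96-fold). Of 48 chromatin regulators, 39 had a peak and 29 passed, led by BRD2 (10.7-fold, on an alternative contig). Next were KDM6B (4.76-fold over 7 fragments, classed as intergenic), SETD5 (4.28-fold over 12 fragments, intron) and DNMT3A (4.17-fold over 6 fragments). Of 33 stress genes, 29 had a peak and 19 passed, led by EIF2AK3 (4.28-fold), PPP1R15A (4.08-fold), CALR (3.73-fold) and HSP90B1 (3.55-fold). In cholesterol and fatty acid synthesis, 17 of 27 had a peak and 12 passed, led by ACACA (5.51-fold, on an alternative contig), DHCR7 (3.30-fold), FDFT1 (3.04-fold) and SCD (2.67-fold). In glycolysis, 15 of 23 had a peak and 11 passed, led by LDHB (5.04-fold), with GPI at 3.29-fold and with best peaks of PFKFB3 and SLC2A1 that did not pass, while another of PFKFB3 did. Of 18 nuclear and non-coding RNAs, 12 had a peak and 9 passed, led by PVT1 (4.76-fold over 7 fragments), SNHG1 (3.41-fold), GAS5 (3.32-fold) and RMRP (3.04-fold). Of 13 mitochondrially encoded mRNAs, COX2 (2.17-fold), CYTB (1.94-fold), COX1 (1.88-fold), ND2 and ND4 held the summit of a peak and all passed. These peaks were wide, such as 7807 to 10075 for COX2 and 10655 to 14780 for ND4. The other mitochondrial mRNAs may therefore lie under a peak without holding its summit. Of 517 zinc finger genes with a ZNF symbol, 171 had a peak and 57 passed. They were led by ZNF275 (6.25-fold), ZNF91 (5.41-fold, classed as intergenic), ZNF597 (5.39-fold over 9 fragments) and ZNF670 (5.20-fold over 12 fragments). The adjusted permutation p-values of the 17 lists other than oxidative phosphorylation and histones ran from 0.315 to 1, and 3 lists with under 5 members with a peak were not tested.

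**Figure D2:**
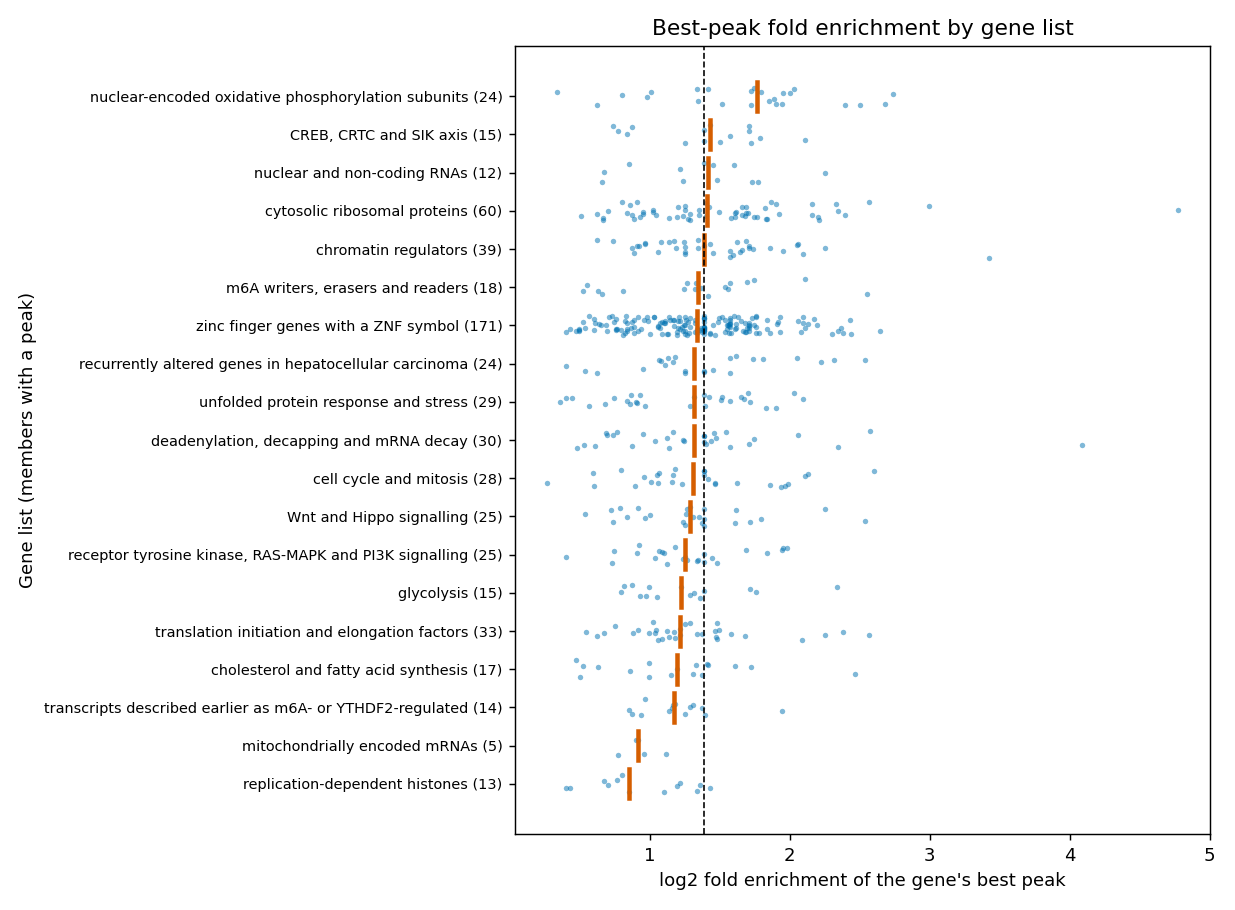
Each point is a gene with a peak, placed by the log2 fold enrichment of its best peak (x axis) in its list (y axis, members with a peak in parentheses), with vertical scatter for legibility. Orange bars are list medians and the dashed line is the median of random lists. Oxidative phosphorylation subunits have the highest median (1.77) and replication-dependent histones the lowest (0.85).

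The last comparison asked how peaks gathered in genes. By the gene that contains the summit, the highest numbers were 24 peaks in PRKCA, a protein kinase C, 21 in PLCB1, 19 in MAGI2, 17 in GRIP1, 16 each in ASAP1 and GALNT13, 15 in SMYD3, 14 in CUX1, and 13 each in ACACA, SEPTIN9 and FNDC3B. In PRKCA 19 of the 24 peaks were intronic, the median was 3 fragments, and 4 peaks lay in its 3' UTR. The 16 peaks of GALNT13 were all classed as intergenic, and those of ACACA, of which 1 was intronic, lay on chromosome 17 and on an alternative contig of it. By the deposited gene, which is that of the nearest transcription start site, BMS1P23 (41 peaks, all intergenic, over 1159 kb of chromosome 2), PRKCA-AS1 (17), RPRM (16), SMYD3 (15), ACO1, SEPTIN9, GRIP1, LOC100133920 and LOC101928381 (13 each) and LINC01619, ACTR3BP2, MAGI2-AS3 and LINC00536 (12 each) led. With a q of 0.01 or less, chosen after seeing the data, the leading genes were FLNA, an actin crosslinker (8 peaks, 7 in exons, folds 1.49 to 2.19), followed by ASPH, EIF4G2, MET, TJP1, SF1, USP9X, EIF3C, PABPC1, HIPK2 and FMN1 with 6 each. Of 8837 deposited genes, 3389 (38.4%) had 2 or more peaks. Genes of any type with a ZNF symbol, not only the protein-coding ones of the list above, did so in 72 of 188 cases (38.3%). Other genes did so in 3317 of 8649 (38.4%; Fisher's exact test, two-sided, p = 1). The deposited gene was the one containing the summit for 54.9% of the 13564 peaks inside a gene.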

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

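No paired analysis was possible because the data are 1 combined peak list with no column per library, so leaving out a replicate was not possible either. The planned settings that need a genome or transcript models (stop codon windows, DRACH motif, strand-aware annotation) were not run. Settings on fragment number, background level, gene assignment, main chromosomes (except for the peak count) and q of 0.01 for lists were chosen after seeing the data. The cause of the changes below was not tested, apart from stricter thresholds leaving fewer peaks. The fold threshold filters on the compared value itself, so it cannot decide whether a difference in fold holds. Of 14858 peaks, 5541 had a −log10 q of at least 2, 3091 one of at least 5, and 1058 a fold of at least 4. The 3' UTR share moved from 27.6% to 36.6% at a −log10 q of at least 5, 18.1% at a fold of at least 4 and 46.0% at 20 or more fragments. The top-minus-bottom 25% difference in that share, -23.5 percentage points, was 3.02 at a fold of at least 4, -8.67 at a −log10 q of at least 5 and -7.66 with 20 or more fragments. The log2 fold difference of 3' UTR from exon peaks was -0.012 at a −log10 q of at least 5, -0.025 at a fold of at least 4 and 0.022 with 20 or more fragments. That from intron peaks was -0.547, -0.031 and -0.482 under these settings and -0.016 within groups of background level. With −log10 q as the measure the differences were 0.478 and 1.91. Genes with 2 or more peaks numbered 427 at a −log10 q of at least 5, 87 at a fold of at least 4 and 1454 with exon and UTR peaks only, and the difference of ZNF from other genes, -0.0534 percentage points, was -12.6, -9.51 and -6.92 under these settings and 4.06 by the gene containing the summit, none passing.

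Of the 2 lists called, 0 passed at a −log10 q of at least 5 and 0 at a q of 0.01 or less on main chromosomes. At a fold of at least 4, where 4 lists could be tested and histones could not, 0 passed, while with the mean over a gene's peaks histones (-0.41) passed and oxidative phosphorylation (0.19) did not. With that mean 3 lists not called before also passed, for a total of 4: translation factors -0.29, Wnt and Hippo -0.29 and cholesterol -0.35. Translation factors (-0.25) also passed when matched on peaks per gene. The lists below turned direction without passing the test under that setting, with these log2 differences. At a −log10 q of at least 5 they were cell cycle 0.34, non-coding RNAs -0.097, carcinoma genes 0.18, stress 0.15 and ZNF genes 0.41. With exon and UTR peaks only they were m6A factors 0.036 and stress 0.031. With the mean over peaks it was the CREB axis, -0.15. With the deposited gene they were the CREB axis -0.13, decay 0.050 and non-coding RNAs -0.15. Against lists matched on background they were cholesterol 0.086, decay 0.012, glycolysis 0.063, m6A factors 0.042, mitochondrial mRNAs 0.0044, carcinoma genes 0.031, translation factors 0.16 and stress 0.18. At a q of 0.01 or less on main chromosomes they were ribosomal proteins -0.012, cell cycle 0.0081, stress 0.0089 and ZNF genes 0.19.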

Other observations

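The tests of scatter over the genome, of fragment numbers behind high folds and of the highest pileup below were chosen after the result was seen. The genes of this paragraph lie outside the fixed lists and were chosen after their values were seen. Among the highest folds, the nearest start site to the peaks of SNHG32 (24.8-fold; chromosome 6, 31839549 to 31839977), NAP1L4 (9.83-fold) and SNRPB (8.34-fold) was that of a small nucleolar RNA, SNORD52, SNORA54 and SNORD119. The SNHG32 peak stood over a background of only 0.533, the genome-wide level, and NAP1L4 is a candidate for shared reads in the second pattern below. Whether the small nucleolar RNAs bear on these folds was not tested. Among the 94 peaks with an input pileup of 200 or more were the 3' UTRs of the caveolin mRNAs CAV2 (1.51-fold) and CAV1 (1.58-fold) and of the thioredoxin reductase TXNRD1 (1.48-fold). HIPK2, a kinase of the DNA damage response, had 5 peaks in its 3' UTR with a q of 0.01 or less, with folds of all its 6 peaks at that q from 1.44 to 1.88. The cytoskeletal genes KRT8 and LMNA had 5 peaks each at that q, in any feature class.

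Weak peaks outside exons were the first pattern: 77.9% of intron and 63.7% of intergenic peaks rested on 4 or fewer fragments, against 6.56% of 3' UTR peaks. Even scatter over the genome was argued against, since the variance of their counts per 1-Mb bin was 2.84 times the mean, and 2.76 times without the fullest bin, on chromosome 2. Protein-coding genes with an exon or UTR peak at a q of 0.01 or less carried a weak intron peak in 426 of 2754 cases (15.5%), and other genes in 965 of 17220 (5.60%), with an odds ratio of 2.56 over 10 groups of gene length (95% bootstrap interval 2.25 to 2.93). Unspliced RNA of transcribed genes may therefore account for part of them, as a hypothesis. Mappability and copy number of the line were not tested, and whether YTHDF2 binds these RNAs stays open without values per library.

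The highest folds were the second pattern: of 74 peaks with a fold of 8 or more, 27 (36.5%) lay on alternative, unplaced or random contigs, which hold 2.17% of all peaks. On main chromosomes, 12 of 122 peaks in genes that also had a peak on such a contig reached this fold, against 26 of 13197 in other genes (Fisher's exact test, p = 4.45e-16, odds ratio 55.3, exact interval 24.7 to 117). Reads shared between copies of a sequence could thus be placed unequally in RIP and input, a candidate explanation for PARN, FMN1, SSBP1, TJP1 and NAP1L4. Some of the high-fold peaks share a gene, as those of TJP1 and those of NAP1L4 do. The Fisher p and the interval treat them as independent and so overstate the precision. Whether a nearly empty background makes the ratio high also stays open: the median of 25 RIP fragments decides nothing, since a fold of 8 itself needs 12, and the median background was 0.814, with 48.6% of these peaks at 1 scaled input fragment or less. True enrichment in the RIP was not separable from these, and copies within the main chromosomes were not tested, which leaves the other genes' 26 peaks open.

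Abundant RNAs were the third pattern: the 94 peaks with an input pileup of 200 or more, among them ribosomal RNA and MALAT1 (1.56-fold), had a median fold of 1.53, and the 6 mitochondrial peaks, not all at that pileup, had folds of 1.62 to 2.17. The highest input pileup was 304, or 0.965 of the 315-bp fragment length, and the highest RIP pileup was 324, which is consistent with a cap of about 1 fragment per position in both. With both at a cap, scaling the input by 0.68 alone gives a fold of 1.47, so such peaks could arise without enrichment. Lower folds on mitochondrial RNA had been expected if folds reflect association with cytosolic YTHDF2. The mitochondrial median was 1.87, against 1.53 in nuclear sets matched on background, with 99.7% of the sets as low or lower. Those sets were matched within 0.1 natural log units of background. The coarser matching of gene lists, by 10 groups of background, gave mitochondrial mRNAs a log2 difference of 0.0044. The 99.7% met the outcome set in advance as counting against association, but that reading was not used. The expectation was wrong as a test, because with no control pulldown in the design the mitochondrial folds give no level for unbound RNA. Association thus stays open for mitochondrial and nuclear RNAs alike.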
